A study of Mus musculus with 7 samples.

How the data were processed

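RNA from 7 mouse brain samples was hybridised, 1 sample per array, to Agilent oligonucleotide arrays of 60-base probes in 1 colour (Cy3), after amplification and labelling with the Low Input Quick Amp kit, per the labels' protocols. The labels gave 3 samples as wild type day 3, 3 as knockout day 3 and 1 as wild type sham, and every sample was placed by its title. Spot intensities were deposited as scanner output of Agilent Feature Extraction 11.5.1.1: per the file headers, the processed intensity had its background subtracted and a spatial and a multiplicative trend removed within each array, with substitute values for dim spots, and no step linked 1 array to another. The deposited value table of the whole series holds a linear ratio, found here to be each array's processed signal divided by its 75th percentile over the spots other than controls, to within 0.0428% at most. The medians of its columns were 0.0942 to 0.107. It was used as an alternative only. Probe positions are those of the array design in the files, on mm9.

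The arrays carried 44397 spots each, 43020 of them other than controls, and 31177 to 34029 of these were flagged by the scanner software as well above background (72.5% to 79.1%). The 75th percentile of the processed signal was 1350 to 1859. No spot was saturated, and 91 to 147 spots per array had an outlier flag and were left out, which removed 28 of 39429 probes altogether. Arrays give no count of molecules, so the number of arrays limits the precision. The slide of each array was taken from the files: the wild type day 3 and sham arrays were on 1 slide and the knockout arrays on another.

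The processed signal was taken to log2 and each array's 75th percentile of it was subtracted. Spots of a probe were averaged; 399 probes had 10 spots. Probes well above background on at least 3 of the 7 arrays were kept and each gene was represented by its probe with the highest mean over the 7 arrays. Accessions in the files were matched, without versions, to a RefSeq gene table of assembly GRCm38.p6 used for names only; 28315 of 39401 probes matched, and the others kept the name in the file. This gave 23311 features, 16313 of them with an ordinary gene symbol. A gene counts as not above background in a group only if all its probes are. There an "at least" fold sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array.

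Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a model of the 3 groups, with 4 residual degrees of freedom that all come from the 6 day 3 arrays and 1.68 prior degrees of freedom. The single sham array is assumed to vary like them. The tests were two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. With 3 arrays against 3, an exact permutation test could not go below p = 0.10, so none was used for single genes. Fixed gene lists, 31 in number with 551 entries of which 531 were measured, covered phospholipases and lipid mediators, the deiminases, injury responses and cell type markers. They were tested with limma's camera (preset correlation 0.01, at least 3 measured members), again with an estimated correlation, and with fry, adjusted over the lists. The knockout comparison had 1 more list, of the 3 genes past the threshold in the mean of both day 3 groups against sham, which was chosen on these samples and was not called (camera, adjusted p = 0.546). Genes whose probe starts within 10 Mb of Pla2g2e were set against all others with Fisher's exact test, two-sided, with a 95% interval of the odds ratio. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

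The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Pla2g2e and Padi4 always and, per comparison, up to 12 genes higher and 12 lower with the largest log2 difference among those past the threshold, with an ordinary symbol and, for knockout against wild type, no overlap between the groups. It fills each direction up to 12 from genes with an unadjusted p under 0.01 that meet the other conditions, which are reported as not passing, and adds per list up to 4 members with the smallest p. Some genes that the rule gives are not reported here. BC002059 has no ordinary symbol and is named because it passed. A few other genes outside the rule are named as chosen after their values were seen. The second probe of Padi4 was tested in a separate limma fit of all 39401 probes, adjusted over them.

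The steps were tested on simulated data for knockout against wild type, with 200 of 23311 features changed. With the spread of the 6 day 3 arrays, limma recovered 0% of changes of 1, 28.4% of changes of 2 and 77.3% of changes of 4 on the log2 scale, with 2 false calls. With the spread found without wild type day 3 replicate 1 it recovered 41.8%, 67.2% and 97.0%, with 5 false calls. In both settings camera found a list of 20 members shifted by 1 and called 0 of 100 unshifted lists; the simulated genes were independent, so this says nothing of lists whose members move together.

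The alternatives were normexp background correction with an offset of 50 of the mean and local background signals, quantile normalisation, centring on the median, the deposited value table, no filter on dim probes, only probes well above background on all 7 arrays, the mean of a gene's probes, eBayes with trend and robust settings, array weights, the replicate number as a block, only the 6 day 3 arrays or only the 4 arrays of the shared slide, and distances of 5 and 20 Mb. Each of the 6 day 3 arrays was also left out in turn. Chosen after seeing the data were fits without the arrays labelled wild type day 3 replicate 1 and sham, and of knockout against all 4 wild type arrays.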

Results

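Gene expression was measured in mouse brain on day 3 after transient middle cerebral artery occlusion, a stroke model in which a filament blocks the main artery of one hemisphere, here for 60 min, before blood flow returns. The mice were males of the C57BL/6N background that either were wild type or lacked Pla2g2e, the gene for a secreted phospholipase A2 that releases fatty acids from phospholipids. There were 3 arrays labelled wild type day 3, 3 labelled knockout day 3 and 1 labelled wild type sham, a control operated on without occlusion. Each sample was hybridised in 1 colour to its own oligonucleotide array with 43020 spots other than controls, of which 31177 to 34029 were well above background. No spot was saturated. The 3 wild type day 3 arrays and the sham array shared 1 slide, and the 3 knockout arrays lay on the other, so slide and genotype cannot be told apart in any comparison of knockout with wild type or sham. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. Signals are given as log2 relative to the 75th percentile of the same array.

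The transcript of Pla2g2e did not separate the arrays by genotype. Its brighter probe, on chromosome 4 at 138438659 to 138438718 of the mm9 assembly, read -6.89, -3.68 and -3.36 on the arrays labelled wild type day 3 replicates 1, 2 and 3. It read -4.44, -5.83 and -4.97 on the arrays labelled knockout day 3 replicates 1, 2 and 3, and -4.69 on the array labelled sham. The lowest of the 7 values thus came from an array labelled wild type. The group means were -4.65 ± 1.95 for wild type and -5.08 ± 0.70 for knockout (SD, n = 3 each), a difference of -0.43 ± 1.02 (SE; limma, adjusted p = 0.889). Without the array labelled wild type day 3 replicate 1 the difference was -1.55 ± 0.44, still short of the threshold after adjustment. The dimmer probe, at 138438368 to 138438427, was not well above background on any knockout array nor on wild type replicate 1. It read -6.72, -6.50 and -6.83 on wild type replicates 2 and 3 and on sham. Which exons the knockout lacks is not given in the sources used here, and a probe outside the deleted part checks nothing. Arrays are therefore named by their labels throughout. Padi4, the gene of a peptidylarginine deiminase that converts arginine in histones to citrulline, was measured by a probe at 140301675 to 140301734 on the same chromosome. Padi4 thus lies 1.86 Mb from Pla2g2e, within the stretch whose genes are compared with all others further below. Its probe read -8.58, -2.69 and -3.55 on wild type replicates 1, 2 and 3. On knockout replicates 1, 2 and 3 it read -5.82, -7.01 and -7.31, and on sham -3.39. The Padi4 difference between knockout and wild type was -1.77 ± 1.59 (SE; limma, adjusted p = 0.862) with all arrays and -3.59 ± 0.54 without wild type replicate 1. This probe was not well above background on wild type replicate 1. A second Padi4 probe, well above background on every array, gave -0.95 ± 0.31 in a fit of all 39401 probes (limma, unadjusted p = 0.0226, adjusted p = 0.936). It read -6.36, -5.95 and -5.52 on wild type replicates 1, 2 and 3 and -5.10 on sham. On knockout replicates 1, 2 and 3 it read -6.51, -7.04 and -7.12, below every wild type array.

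**Figure D1:**
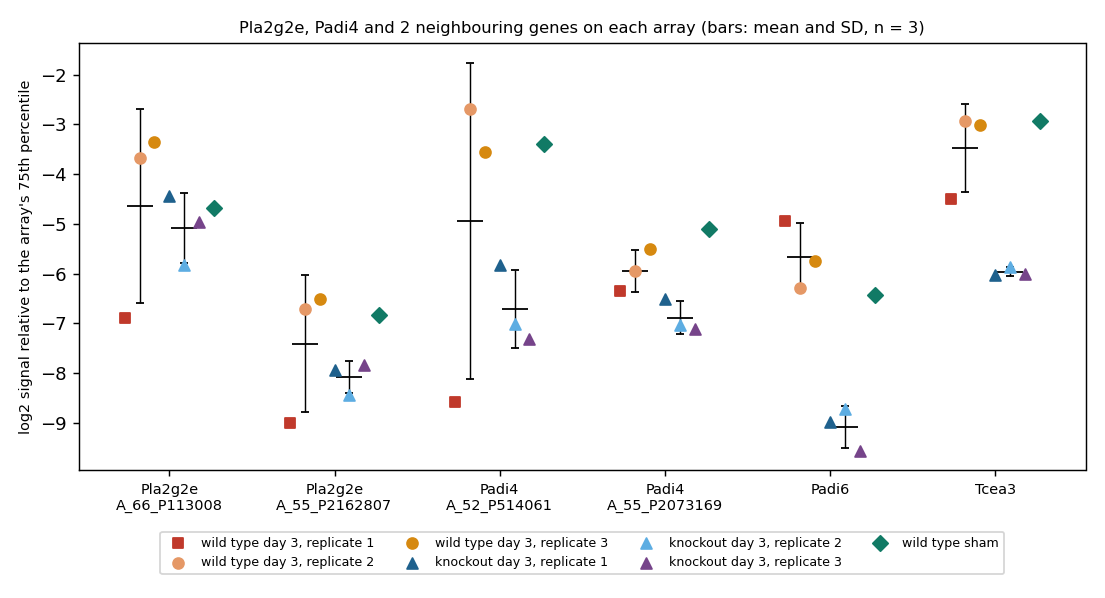
Log2 signal relative to the array's 75th percentile (vertical axis) for both probes each of Pla2g2e and Padi4 and for 2 neighbouring genes (horizontal axis). Each point is 1 of the 7 arrays, with the mean and SD of the 3 arrays labelled wild type day 3 and of the 3 labelled knockout day 3. The brighter Pla2g2e probe overlaps between the genotypes.

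The array labelled wild type day 3 replicate 1 differed from the other 6 in genes of injured brain and of neurons. Spp1, which encodes the secreted phagocyte and matrix protein osteopontin, read -2.66 on it against 4.84 to 5.65 on the other 6 arrays, sham included, a level 181-fold below the lowest of them. Lgals3, the gene of a galectin of activated phagocytes, read -3.17 against 5.77 to 6.27, and Gpnmb, a glycoprotein gene of lipid-laden phagocytes, -6.08 against 2.48 to 3.28. Serpina3n and Lcn2, secreted proteins of reactive astrocytes, read -3.55 against 2.64 to 3.49 and -3.54 against 1.97 to 4.11. In the other direction, Ppp1r1b, which encodes the dopamine signalling protein DARPP-32 of striatal neurons, read 5.84 against 0.07 to 3.03. All members of the fixed lists of reactive astrocyte genes (24), cell cycle genes (25) and monocyte and macrophage genes (15) were lower on this array than on each of the other 6. All members of the lists of neurons (18), striatal neurons (13) and synaptic genes (28) were higher on it than on each of the other 6. By list medians it lay below the other 5 day 3 arrays in 18 of 31 lists and above them in 8. The array labelled sham lay within those 5 arrays in 14 lists, among them the damage-associated microglia, reactive astrocyte and inflammatory cytokine lists. It lay below them in 11, among them extracellular matrix (1.58 against 2.11 to 2.97) and red blood cell genes (-4.94 against -2.58 to -0.43), and above them in 6. The correlation of log2 signals across genes was 0.857 to 0.916 between wild type replicate 1 and any other array and 0.968 to 0.991 for the 15 other pairs; genes are not independent replicates. Spp1, Lgals3, Gpnmb and Ppp1r1b were chosen after their values were seen.

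**Figure D2:**
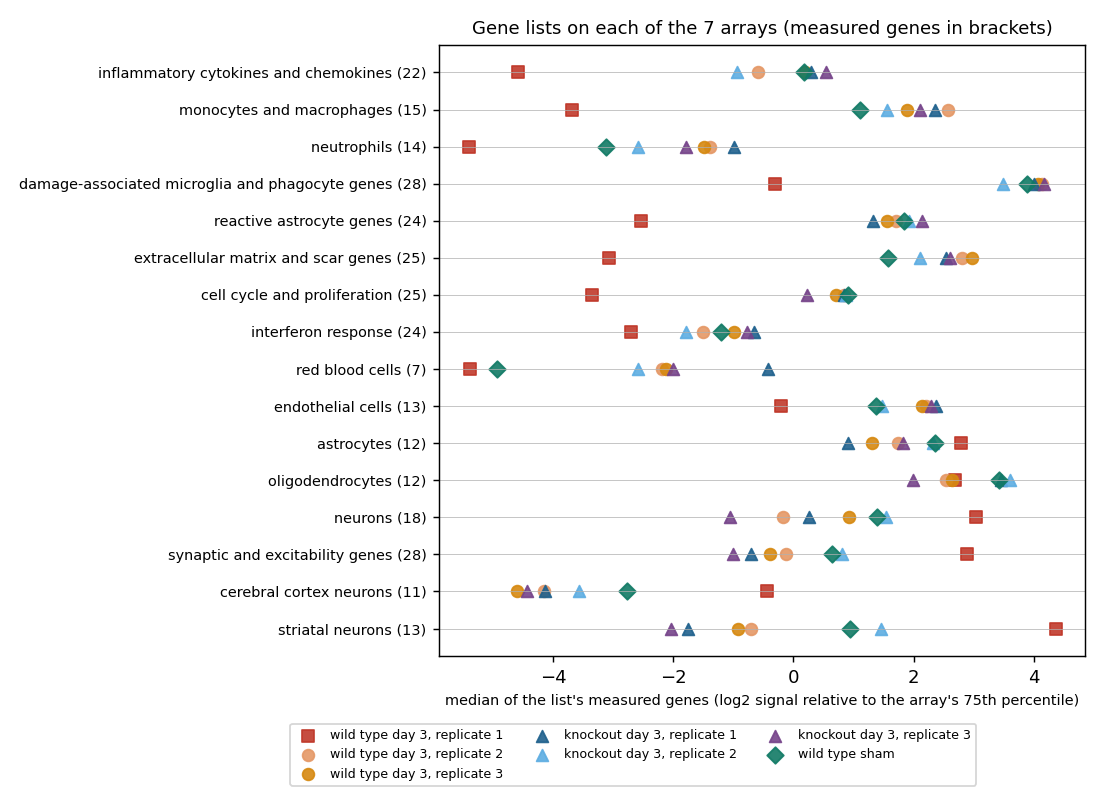
Median log2 signal, relative to the array's 75th percentile, of the measured genes of 16 lists (horizontal axis) on each of the 7 arrays, with 1 point per array. The array labelled wild type day 3 replicate 1 lies at -0.31 for damage-associated microglia and phagocyte genes, where the other 6 arrays lie at 3.49 to 4.17, and at 4.37 for striatal neurons, where they lie at -2.04 to 1.46.

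The comparison of knockout with wild type at day 3 asks whether loss of Pla2g2e alters gene expression in the injured brain. Among the genes that separated the 2 genotypes were Padi6 and Tcea3, neighbours of Pla2g2e, and Cnn1, which lies on chromosome 9. Padi6, a peptidylarginine deiminase gene known from oocytes, was well above background on the 3 wild type arrays (-5.66 ± 0.67, SD) and on no knockout array, at least 3.30-fold lower in knockout. Tcea3, which encodes a transcription elongation factor, read -5.96 ± 0.09 in knockout and -3.48 ± 0.88 in wild type, and Cnn1, the smooth muscle gene calponin, read -3.92 ± 0.18 in knockout and -2.11 ± 0.73 in wild type (SD, n = 3). None of these passed the test: limma called 0 of 23311 genes at an adjusted p under 0.05, and the smallest over all genes was 0.141.

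Beyond these 3, the rule for named genes gave, on the lower side, the axon guidance receptor gene Unc5d at -2.06 ± 0.48 (log2 difference and SE), the homeobox gene Dlx4 at -1.54 ± 0.25 and the tubulin ligase gene Ttll6 at -0.97 ± 0.20, with a limma adjusted p of 0.862 each. Tchhl1, Lcn11, Vmn1r63, Olfr620 and Olfr59, all lower, were not well above background on any knockout array. Btn2a2, a butyrophilin gene, was lower on its brighter probe, which was not well above background on any knockout array, and differed by 0.73 when the fit held only the 6 day 3 arrays and another of its probes became the brightest. An unadjusted p under 0.05 was found for 197 genes, where 1165.6 would be expected by chance. Of the 197, 23 were at least 2-fold higher and 71 at least 2-fold lower in knockout. The arrays of the 2 genotypes did not overlap in 1056 genes, 4.53% of those tested, where chance gives 10%. Without wild type replicate 1, limma again called 0 genes, with 380 at an unadjusted p under 0.05 and the smallest adjusted p at 0.105 (Tcea3). With array weights, which gave that array 0.0609 and did not fully converge, 1306 genes had an unadjusted p under 0.05. The count of 197 thus depended on wild type replicate 1 and does not show less difference than chance.

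Taken as labelled, lists of injured brain were higher in knockout than in wild type and lists of neurons lower, differences that were mostly smaller or absent without wild type replicate 1. Inflammatory cytokine and chemokine genes had a median log2 difference of 1.52, with 21 of 22 members higher. Cxcl10, an interferon-induced chemokine, differed by 1.52 ± 0.93 (SE) and Il1a by 1.12 ± 0.48. Reactive astrocyte genes had a median of 1.39 with 24 of 24 higher, with Lcn2 at 2.76 ± 1.80 and Serpina3n at 2.55 ± 1.75. Damage-associated microglia and phagocyte genes had a median of 1.05 with 28 of 28 higher, with the lysozyme gene Lyz2 at 2.15 ± 1.69 and the microglial adaptor gene Tyrobp at 1.27 ± 0.98. The medians of monocyte and macrophage, cell cycle, extracellular matrix and interferon response genes were 1.58, 1.32, 1.27 and 0.67. Synaptic and excitability genes had a median of -1.19 with 28 of 28 lower, with the synaptic vesicle genes Syt1 at -1.19 ± 0.75 and Syn1 at -1.35 ± 0.88. Striatal neuron genes had a median of -1.58 with 13 of 13 lower, among them the tachykinin gene Tac1 at -2.13 ± 1.42.

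Of the 32 lists tested, limma's camera with its preset correlation called 12 higher and 6 lower, with adjusted p from 3.98e-07 for the synaptic, microglia and cell cycle lists to 0.0253 for the peptidylarginine deiminases. With an estimated correlation no list passed, the smallest adjusted p being 0.623, and with fry none passed either, the smallest adjusted p being 0.237, with 1 list at an unadjusted p under 0.05. The other lists called higher were red blood cells (median 1.51), endothelial cells (0.84), homeostatic microglia (0.42), polyunsaturated fatty acid and oxylipin genes (0.30) and cholesterol biosynthesis (0.19). The others called lower were cerebral cortex neurons (-1.38), neurons (-1.22), peptidylarginine deiminases (-0.93) and hypothalamic neurons (-0.91). Secreted and cytosolic phospholipase A2 genes (median -0.02, camera adjusted p = 0.744) and neural repair genes (-0.16, adjusted p = 0.593) were not called. No member of any list passed over all genes, and 1 passed when adjusted over the list alone, Padi6 among the deiminases. Padi6, Padi4 and Padi3 of that list lie 1.84 to 1.90 Mb from Pla2g2e.

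Without the arrays labelled wild type day 3 replicate 1 and sham, a fit chosen after seeing the data, most lists of injury and neurons differed less. The medians became -0.05 for cytokines and chemokines, -0.06 for reactive astrocyte genes, -0.02 for damage-associated microglia and phagocyte genes, -0.12 for monocytes and macrophages, -0.10 for synaptic genes and -0.11 for striatal neurons, none of them called. Other neuron lists stayed lower in knockout without being called, hypothalamic neurons at -0.65 with 7 of 9 members lower (camera, adjusted p = 0.0536), neurons at -0.36 with 13 of 18 lower and cerebral cortex neurons at -0.22. Cholesterol biosynthesis genes were called higher in knockout, with a median of 0.30, 19 of 20 members higher (camera, adjusted p = 4.73e-07), a call lost with an estimated correlation (adjusted p = 0.971). Among them were the sterol desaturase gene Sc5d at 0.35 and the lanosterol demethylase gene Cyp51 at 0.49. The deiminases were called lower with a median of -2.05 (camera, adjusted p = 8.86e-06), a call likewise lost (adjusted p = 0.971). Among them were Padi4 at -3.59, Padi3 at -2.05 and Padi6, below background on every knockout array, with Padi2 and Padi1 at 0.24 and 0.12. Padi4, Padi3 and Padi6 lie 1.84 to 1.90 Mb from Pla2g2e, so this call cannot be told apart from the differences of genes near it. Also called lower were extracellular matrix genes (-0.19), pericyte and fibroblast genes (-0.24), neutrophil genes (-0.30) and cell cycle genes (-0.12). With an estimated correlation none of these 6 lists passed (smallest adjusted p = 0.971), and 4 list entries passed when adjusted over the list alone against 0 over all genes, the 3 deiminases and Padi4 again among neural repair genes.

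Genes near Pla2g2e on chromosome 4 differed between the genotypes more often than other genes. Of 384 genes tested within 10 Mb of it, 13 had an unadjusted p under 0.05 (3.39%), against 184 of 22927 elsewhere (0.803%), an odds ratio of 4.33 with a 95% interval of 2.24 to 7.68 (Fisher's exact test with genes as units, two-sided, p = 2.53e-05). They went both ways, with 5 higher and 8 lower in knockout. Padi6 lies 1.84 Mb from Pla2g2e on one side, and Tcea3 lies 2.63 Mb away on the other. Pax7, a muscle and neural crest transcription factor gene, differed by -0.88 and Zbtb17, which encodes the MYC partner MIZ1, by -1.45. Without wild type replicate 1 the share was 6.25% near Pla2g2e (24 of 384, 20 of them lower) and 1.55% elsewhere (Fisher's exact test, p = 2.35e-08), and without knockout replicate 3 it was 2.08%. The genes then included Padi4, Padi3 and Pdpn, which encodes podoplanin, a membrane glycoprotein of lymphatic vessels and reactive astrocytes, at -1.72; Pax7, Zbtb17 and Pdpn were chosen after their values were seen. No near gene passed limma's adjusted p of 0.05 in either fit, and slide and genotype cannot be told apart.

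The comparison of wild type day 3 with sham, within 1 slide, asks which genes the occlusion altered. Zfp652, a zinc finger gene, read -1.81 ± 0.57 in wild type day 3 (SD, n = 3) and was not well above background on the 1 sham array, at least 54.5-fold higher at day 3. Cnot9, a subunit gene of the CCR4-NOT complex that shortens mRNA tails, read -3.44 ± 0.33 and was likewise below background on sham, at least 17.7-fold higher. BC002059, a gene known by its clone name, was below background on sham too, at least 39.0-fold higher. These 3 were the only genes that rose in limma's test (adjusted p = 0.0484 each) and 0 fell, with 261 genes at an unadjusted p under 0.05; the sham array has no replicate and is assumed to vary like the day 3 arrays. Each of the 3 is measured by 1 probe, and the 3 spots lie at rows 528 to 531 and columns 24 to 25 of an array of 532 rows and 85 columns. The count was 6 without wild type replicate 1 and 0 without wild type replicate 2 or 3 or any 1 of the knockout arrays, which share the estimate of the spread. It was 0 with normexp background correction or quantile normalisation.

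The genes that filled the named list without passing included Raver1, an RNA-binding protein gene, at 4.28 ± 0.47 (log2 difference and SE; limma, adjusted p = 0.508), the adaptor gene Dok2 of blood cells at 4.53 ± 0.92 (adjusted p = 1.0) and the epidermal transcription factor gene Grhl3, below background on sham and at least 8.31-fold higher (adjusted p = 0.508). Lower than sham without passing were Pmch, the gene of melanin-concentrating hormone in the hypothalamus, at -3.21 ± 0.77, the T-box gene Eomes at -2.49 ± 0.44, the homeobox gene Irx1 at -1.84 ± 0.41 and Secisbp2l at -1.22 ± 0.27, with Lrcol1 at -3.49 ± 0.52 and Lrit3 at -1.94 ± 0.41, each above background on 1 of 3 wild type arrays. Also named by the rule, Olfr1466, Fads6 and Chp2 were higher by 2.81 to 3.09 without passing, and Lrrc14b, Olfr1099 and Ppp1r1c, below background on sham, at least 6.55-, 1.88- and 1.98-fold. The spots of Raver1, Dok2, Grhl3, Lrrc14b and Fads6 are among the 23 that were low on the sham array alone, as are those of the 3 genes that passed, and a local defect of that array may account for these differences.

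As labelled, lists of injured brain were lower in wild type day 3 than in sham, in a mean that includes wild type replicate 1. Inflammatory cytokines and chemokines had a median log2 difference of -1.10 with 20 of 22 lower, among them Cxcl10 at -3.38 ± 1.31 (SE). Reactive astrocyte genes had a median of -1.15 with 24 of 24 lower, among them the complement gene C3 at -2.95 ± 1.93. The medians were -1.54 for cell cycle, -1.02 for damage-associated microglia, -1.21 for monocytes and macrophages, -0.75 for interferon response, -1.08 for oligodendrocyte precursors and -0.65 for oligodendrocytes. The precursor transcription factor gene Olig2 stood at -1.15 ± 0.47 and the myelin gene Cldn11 at -0.98 ± 0.65. Red blood cell genes had a median of 1.78 with 7 of 7 higher, among them the globin gene Hba-a1 at 1.78 ± 1.30. Neutrophil genes had a median of 0.50 with the lactoferrin gene Ltf at 2.11 ± 0.54, and oxidative phosphorylation genes one of 0.19 with 25 of 26 higher, among them the complex I gene Ndufa9 at 0.83 ± 0.27.

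Camera called 5 of 31 lists higher and 10 lower in wild type day 3, and 0 with an estimated correlation (smallest adjusted p = 0.652) or with fry (smallest adjusted p = 0.996; 0 at an unadjusted p under 0.05). No list member passed over all genes or adjusted over the list alone. Without wild type replicate 1 the medians became 0.33 for cytokines and chemokines, 0.29 for reactive astrocyte genes, 0.07 for damage-associated microglia and 0.36 for monocytes and macrophages, none of them called. Camera then called 6 lists higher, among them extracellular matrix (0.94), neutrophils (2.06), endothelial cells (0.98) and red blood cells (2.67), and 7 lower, among them synaptic genes (-0.93), striatal neurons (-1.54), neurons (-0.75) and astrocytes (-0.46). Their smallest adjusted p with an estimated correlation was 0.680, and 15 list entries passed when adjusted over the list alone against 0 over all genes. Oligodendrocyte and precursor lists then had medians of -0.73 and -1.03.

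Against sham, the arrays labelled knockout day 3 showed the same 3 genes higher, Zfp652 at least 66.1-fold, Cnot9 at least 21.6-fold and BC002059 at least 34.4-fold (limma, adjusted p = 0.0396 each), and 0 lower, with 304 genes at an unadjusted p under 0.05. Ang4, an angiogenin gene, stood at 4.87 ± 1.09 (log2 difference and SE), but its spot is another of the 23 low on the sham array alone. On the lower side stood Cnn1 at -3.20 ± 0.56 and Tcea3 at -3.03 ± 0.65, with Padi6 and Vmn1r49, below background on all knockout arrays, at least 1.93- and 5.25-fold lower. Kctd7, Xlr3b and Rhox3f were lower by -2.59 to -1.02, and Spint3, below background on sham, at least 1.88-fold higher. None of these passed. Both comparisons use the 1 sham array, and the 3 shared genes were low on it alone. Zfp652, Cnot9 and BC002059 read -9.37, -9.37 and -7.50 on it, against -2.47, -3.81 and -2.45 at the lowest on any other array. Both sets of calls thus rest on the same low sham values. Simulated unchanged groups that shared a sham array gave 0.02 calls on average in 50 draws. The 0 calls they shared are too few to measure the overlap that a shared array brings. Independent lists of this size would share 0.000386. The count was 8 without wild type replicate 1, 0 without any other single day 3 array, and 0 with normexp or quantile normalisation.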

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

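The fits without both doubted arrays (wild type day 3 replicate 1 and sham) and of knockout against all 4 wild type arrays were chosen after the results were seen; the others were planned. For knockout against wild type the count of genes was 0 in every fit by limma's adjusted p, including each left-out array, except 2 with array weights and 1 against all 4 wild type arrays. It was 94 by the looser criterion of an unadjusted p under 0.05 with a 2-fold difference. The array weights, whose estimation did not fully converge, were 0.0609 for wild type replicate 1 and 6.80 for replicate 2. For wild type day 3 against sham the 3 genes became 0 with normexp, quantile normalisation, probes well above background on all 7 arrays, trend and robust settings, or the 4 arrays of the shared slide, 1 with median centring, 7 with array weights, and 0 to 6 with 1 array left out. For knockout against sham they became 0 with normexp, quantile normalisation, median centring or probes above background on all 7 arrays, 10 with array weights, and 0 to 8 with 1 array left out. The filter on all 7 arrays removes genes that are below background on sham by its construction; the other causes were not tested. Median centring moved the median of all genes in wild type against sham from 0.03 to 0.13.

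The 18 lists called for knockout against wild type became 10 with array weights, 6 without both doubted arrays, 0 with an estimated correlation or fry, and 6 to 19 with 1 array left out. For wild type against sham the 15 lists became 0 with an estimated correlation or fry. Without both doubted arrays the knockout difference turned to -0.0457 for cytokines, -0.0249 for damage-associated microglia, -0.0589 for reactive astrocytes, -0.12 for cell cycle, -0.19 for extracellular matrix and -0.12 for monocytes. With 1 array left out their medians ran from -0.0457 to 2.37, -0.0249 to 1.65, -0.0589 to 2.14, -0.12 to 2.02, -0.19 to 2.15 and -0.12 to 2.51. The median of neural repair genes ran from -0.27 to -0.10, and its test changed direction once. With array weights the direction of the test turned for cell cycle (-0.12) and extracellular matrix (median 0.0463). Against sham, wild type turned higher with array weights for cytokines (0.25), damage-associated microglia (0.10), reactive astrocytes (0.23) and monocytes (0.48). With 1 array left out these ran from -1.96 to 0.33, -1.59 to 0.0706, -1.86 to 0.29 and -1.87 to 0.36. Apart from neural repair, the lists turned only in fits that leave out or weigh down wild type replicate 1; the cause was not tested otherwise. Pla2g2e ran from -1.55 to 0.21 with 1 array left out, turning without wild type replicate 2 (0.0482) or 3 (0.21), and Btn2a2 turned to 0.73 with only the 6 day 3 arrays, where another probe was used.

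The share of genes near Pla2g2e stayed above that elsewhere in each alternative run, from 1.56% with normexp to 11.2% with array weights. With the replicate block the counts were 0 genes and 19 lists, the share 3.39% and Pla2g2e -0.43. Deviations of same-numbered arrays from their group means correlated across genes with r of -0.380, -0.556 and 0.353. Wild type replicates 2 and 3 gave nearly the same r with each knockout array (0.317 and 0.374, -0.556 and -0.547, 0.411 and 0.353). Both are set against a mean that holds the outlying replicate 1, so this check cannot show whether the number pairs the samples. Of 420 values of single lists under alternatives 362 stayed on their side of the threshold, 35 lost the call and 23 turned. Of 905 of named genes 855 stayed, 36 lost it, 13 gained it and 1 turned. For knockout against wild type, the planned fit without wild type replicate 1 gave the same values as the fit without both doubted arrays. These totals count such values under both fits. Between 72.5% and 79.1% of spots were well above background, and genes below it give only bounds.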

Other observations

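All tests in this part were chosen after the values were seen, except the counts of other splits of the samples.

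Beyond the lists of injury, the arrays other than wild type replicate 1 differed in myelin, neuron and blood genes. Oligodendrocyte genes, those of the myelin-forming cells, had medians of 2.54 and 2.64 on wild type replicates 2 and 3 and of 3.46, 3.61 and 1.99 on knockout replicates 1, 2 and 3. Striatal neuron genes stood at -0.70 and -0.92 on the former and at -1.75, 1.46 and -2.04 on the latter. Red blood cell genes lay at -4.94 on sham, nearer to the -5.38 of wild type replicate 1 than to the -2.58 to -0.43 of the other 5. Cerebral cortex neuron genes were highest on wild type replicate 1 (-0.44) and next on sham (-2.78), above the -4.60 to -3.56 of the other 5.

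The first pattern is that the array labelled wild type day 3 replicate 1 lay below all other arrays in 6 of 6 lists of injured brain, while the array labelled sham lay within the other 5 day 3 arrays in 3 of them, below in 2 (extracellular matrix and monocytes) and above in 1. Low signal on replicate 1 is argued against by its 34029 spots well above background, the most of the 7 arrays. An exchange of these 2 labels is a candidate explanation for those 6 lists. Across genes, sham correlated with the other 5 day 3 arrays at 0.968 to 0.991 and with replicate 1 at 0.916. Its pair with knockout replicate 2 (0.991) was the closest of all pairs of arrays. By the bound first written, sham below the other 5 in 2 lists or more, both an exchange and the explanation that follows would have been argued against; the bound was replaced after that outcome was seen, because 1 array of 6 is lowest in 2 or more of 6 lists with a probability of 0.263 by chance if the lists were independent, which they are not. Little injury in 1 occluded brain with injury in the brain labelled sham, the labels being right, cannot be told apart from an exchange (2 lists), and sham also lay outside the range of the other 5 in 17 of 31 lists, where chance gives 10.3 and the others gave 4 to 14.

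The second pattern is the share of genes near Pla2g2e that differed between the genotypes. A difference between the slides as the whole of it is argued against, since it would not favour 1 stretch of chromosome 4 and the lower bound of the odds ratio was 2.24. Alleles of another strain carried along with the targeted locus may account for it. The genome was cut into 47 windows of 384 neighbouring genes, the stretch around Pla2g2e included. Of these, 0 held as many genes with an unadjusted p under 0.05 as the 13 around Pla2g2e. The highest held 9 and the median was 3. Windows could share genes with that stretch, and the count does not separate causes tied to it. Whether changed probe sites in such alleles contributed was not tested. Counted instead as genes with no overlap between the 3 knockout and all 4 wild type arrays, the share was 5.47% near Pla2g2e and 2.98% elsewhere, where chance gives 5.71% (Fisher's exact test, p = 0.00949). An effect of the lost Pla2g2e product on these 13 genes cannot be told apart from such alleles, because the same samples carry the deletion and its neighbourhood. The same holds for Padi4 and Padi3, 1.86 and 1.90 Mb from Pla2g2e. By the probe that stands for each gene they are not among the 13 but reached an unadjusted p under 0.05 in limma without wild type replicate 1. The second probe of Padi4 reached it with all arrays (limma, unadjusted p = 0.0226).

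The third pattern is that the 3 genes called against sham, Zfp652, Cnot9 and BC002059, were low on the sham array alone, as were Grhl3, Dok2, Lrrc14b, Fads6, Raver1 and Ang4 among the genes named without passing. A local defect of spots on that array is a candidate explanation: of 23 spots lower on it than on each other array by over 2 on the log2 scale, 16 had another within 3 rows and columns, where 1000 random draws of as many spots gave 2 at their upper 95% bound and 6 at most, and the array had 16 spots with a non-uniformity flag against 1 to 3 on the others. Such neighbours also occurred elsewhere: 3 of 7 low spots had one on wild type replicate 2 and 2 of 4 on knockout replicate 1. Each count was above an upper 95% random bound of 0 but not above the random maximum, which was 4 and 2. On knockout replicates 2 and 3, 0 of 3 and 0 of 25 had one. Wild type replicate 3 had 0 low spots, and wild type replicate 1 was not counted. A difference between sham and day 3 brains as the source of these low spots is argued against by the 69.6% of them that lay next to another.

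In the 10 splits of the 6 day 3 arrays into 3 and 3, too few for a share under 0.05, the real split gave 0 genes and the highest other 0, so that 10 of 10, the real one included, gave as many. For lists the real split gave 18 and the others 15 to 19, with 5 as large, the real one included. About as many lists were thus called however the genotypes were mixed, so their number does not set the genotypes apart. For the share of genes near Pla2g2e it gave 3.39% and the highest other 6.51%, with 3 as large; the odds ratio of that other split was 0.955, against 4.33 in the real one, whose next highest was 1.95.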
